A study of Mus musculus with 6 samples.

How the data were processed

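RNA sequencing of total RNA from LPS-treated bone-marrow-derived macrophages of C57BL/6 mice was deposited as 1 table of 54532 genes per sample, for 3 samples labelled siNC and 3 labelled siCXCR4. In 5 tables the authors deposited normalized values, read here as FPKM, reads or fragments per kilobase of gene length scaled to the library's total reads; the file headers give no unit, and FPKM and RPKM cannot be told apart. The unit was worked out from the values, since each value times the gene length was a whole multiple of 1 step per library, within a tolerance of 0.05. In the table of siNC replicate 3 the deposited values are unnormalized whole read counts per gene. The aligner, the counting tool, the strand setting and the handling of reads matching several places are not given in the sources used here. The submitters' notes name the genome build mm9, but 53585 of 54495 genes shared with the GRCm38 annotation (98.3%) had the same position, so positions are given in GRCm38 coordinates.

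Whole reads were worked back from FPKM. The counts deposited as siNC replicate 3 equalled the whole reads of siNC replicate 2 in all 19072 genes with reads, under the same column name, so the pair was taken as 1 library. The design had been planned on 6 libraries with 3 per group, and 5 distinct libraries remained, 2 siNC and 3 siCXCR4. Library totals ran from 18890751 to 21780840 reads in genes. The median half-width of the 95% interval of a log2 fold change was 0.17. Read ranges cover counting error only, and reads without molecular identifiers are not independent molecules.

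The comparison of siCXCR4 with siNC used limma 3.58.1 in R 4.3.3, with a trend and robust estimate, on log2(FPKM + 1) of the 9943 genes with a mean of at least 1 FPKM, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Of several entries with 1 symbol (102 symbols), the one with the highest mean was kept. Cxcr4 was also tested with an exact two-sided permutation test, which cannot go below 0.1 here. On the whole reads, edgeR 4.0.16 (TMM, quasi-likelihood) was chosen beforehand as another test, and DESeq2 1.42.0 and limma-voom were added after the data were seen, as were the copy counted as a separate replicate and the edgeR test with each library left out. The 30 gene lists were tested with camera (preset correlation 0.01, at least 5 measured genes, Benjamini-Hochberg over 28 lists), with an estimated correlation, fry and ranks as alternatives. Other alternatives were quantile normalization, median scaling, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 0.01, limma without trend or robust estimate, library weights, summed entries, a replicate block, an adjusted p under 0.1, a 2-fold threshold and each library left out. The lists, the tests and these alternatives, except those named as added, were chosen before the data were examined.

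Genes were named by rule: Cxcr4; up to 12 genes in each direction past the threshold with groups that do not overlap or, where none pass, the 6 of lowest p in each direction; and of each list up to 4 members of lowest p, up to 6 for a called list, with the most abundant member for other cell types. Predicted genes and small noncoding RNA genes were left out of the first part.

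Both tests were tested on simulated data, in 5 simulations with the sizes of these groups and, over all simulations together, 250 planted genes per fold. By limma 16% of genes planted at 1.25-fold, 72.4% at 1.5-fold and 88.4% at 2-fold were recovered, and 8.65% of calls were false. By edgeR these were 42%, 83.6% and 94.8%, with 4.80% of calls false. A list of ribosomal proteins planted at 0.9-fold was called by camera in 5 of 5 simulations, and 0 of 135 tests of other lists were called. The simulated genes varied independently, with no structure in expression among libraries beyond the planted changes. In the data the estimated correlation of the ribosomal list was 0.79, so the simulations do not show how often camera calls lists falsely here. For edgeR, a split of the real libraries other than the labelled one gave 244 calls. The recovery and false-call shares of both gene tests therefore hold only for libraries without such structure. The false-call shares also leave out calls of the planted ribosomal genes.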

Results

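Gene expression was measured by RNA sequencing in bone-marrow-derived macrophages of C57BL/6 mice, phagocytes grown in culture from marrow precursors. Per the labels, the cells had been transfected with a small interfering RNA (siRNA) against Cxcr4 (siCXCR4) or with a negative-control siRNA (siNC), and all had then received lipopolysaccharide (LPS), a bacterial cell-wall component that activates macrophages through the receptor TLR4, at 100 ng/ml for 12 hours. The series title calls the macrophages monocyte-derived, while the labels of the samples call them bone-marrow-derived, as written here. The deposited columns carry names that begin with wt for siNC and mko for siCXCR4; what mko stands for, such as a knockout, is not given in the sources used here, so the groups are named as the labels give them. The labels name 3 samples per group. The sample labelled siNC replicate 3 held whole read counts that equalled, in all 19072 genes with reads, the reads worked back from the FPKM of siNC replicate 2. The pair therefore differed by less than the sampling noise and was counted as 1 sample. Every other pair of libraries differed, with a chi-square per gene between 4.16 and 11.3. The comparison below rests on 2 siNC and 3 siCXCR4 libraries. The siNC libraries held 21443370 and 19292520 reads in genes, and the siCXCR4 libraries held 21780840, 19323985 and 18890751. Means are given as FPKM ± SD, with n = 2 for siNC and n = 3 for siCXCR4 throughout, and log2 fold changes are siCXCR4 minus siNC on the log2(FPKM + 1) scale. Nothing in the labels says whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

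The first question was how far the siRNA target itself differed. Cxcr4 (ENSMUSG00000045382), the receptor for the chemokine CXCL12, was at 41.7 ± 0.616 FPKM in siNC (n = 2) and 33.4 ± 2.62 FPKM in siCXCR4 (n = 3). The siNC libraries had 41.3 and 42.1 FPKM and the siCXCR4 libraries 31.1, 36.2 and 32.7 FPKM, so all 3 siCXCR4 values lay below both siNC values. These values rest on 1133 to 1646 reads per library. The gene lies on the minus strand of chromosome 1 at 128588199 to 128592293 in GRCm38 coordinates, and the value counts reads over its exons as a whole. The log2 fold change of Cxcr4 was -0.32 (SE 0.0704, 95% interval -0.48 to -0.15), with an adjusted p of 0.457 by limma, so the difference did not pass the test over all genes. A two-sided exact permutation test gave p = 0.1, the smallest p that 2 libraries against 3 allow. On the whole reads, edgeR's quasi-likelihood test gave an adjusted p of 0.0637 for Cxcr4 and DESeq2, added after the data were seen, gave 0.0496. Over all alternatives the adjusted p ran from 0.0496 to 0.866. By size of the fall, Cxcr4 stood at place 235 among 9943 genes tested, and by p at place 63.

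The second question was which other genes differed between siCXCR4 and siNC macrophages under LPS. Among the genes with the lowest p, Ch25h, the enzyme that makes 25-hydroxycholesterol, was at 9.43 ± 0.272 FPKM in siNC and 13.9 ± 1.06 FPKM in siCXCR4. Mfge8, a secreted bridge between apoptotic cells and phagocytes, was at 71.1 ± 0.353 and 90.8 ± 4.64 FPKM, and Mknk2, a kinase that phosphorylates the translation factor eIF4E, was at 20.9 ± 0.144 and 26.5 ± 0.678 FPKM. In the other direction, Cd1d1, which presents lipid antigens to natural killer T cells, was at 7.12 ± 0.383 FPKM in siNC and 4.77 ± 0.228 FPKM in siCXCR4. Malat1, a long noncoding RNA retained in the nucleus, was at 83.3 ± 3.78 and 61.0 ± 3.99 FPKM. By limma none of these passed the threshold: 0 of 9943 genes tested had an adjusted p under 0.05, and the smallest adjusted p was 0.389. At an unadjusted p under 0.05 there were 929 genes (577 higher and 352 lower in siCXCR4), where 497 would be expected by chance. By edgeR with TMM scaling there were 1245 such genes (571 higher and 674 lower), where 640 would be expected. The balance of directions thus differed between the tests and their scaling. The FPKM denominators, worked back from the values, also counted reads outside the listed genes. These were 2.80% and 2.15% of the denominator in the siNC libraries, and 0.00033%, 0.312% and 1.37% in the siCXCR4 libraries. Relative to reads in genes, this lowers the FPKM of every gene more in siNC than in siCXCR4. On the whole reads, edgeR called 17 of 12794 genes, DESeq2 34 and limma-voom 12, the last pair of tools added after the data were seen. In 2769 genes (27.8%) the values of the groups did not overlap, where chance gives 20% for 2 libraries against 3. Genes do not vary independently across 5 libraries, so an excess over these expected numbers is no measure of a group effect. Setting siCXCR4 replicates 1 and 3 against the rest gave 1394 genes at an unadjusted p under 0.05 by limma.

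The remaining genes of the lowest p in each direction were Fam129b, Dhrs3 and Cdt1 (higher in siCXCR4) and Adgb, Ms4a4d, Rps28 and Pilrb2 (lower). Dhrs3, which reduces retinaldehyde, had a log2 fold change of 0.43 (SE 0.0663), Fam129b 0.32 (SE 0.0472) and Cdt1, a DNA replication licensing factor, 0.40 (SE 0.0656). For Ch25h the log2 fold change was 0.51 (SE 0.0715), for Mknk2 0.33 (SE 0.0481) and for Mfge8 0.35 (SE 0.0573). Cd1d1 had a log2 fold change of -0.49 (SE 0.0641), Malat1 -0.45 (SE 0.0675), Adgb -0.35 (SE 0.0486), Rps28 -0.40 (SE 0.0677) and Pilrb2 -0.30 (SE 0.0519). Ms4a4d, at 1.52 ± 0.0761 FPKM in siNC and 0.692 ± 0.109 FPKM in siCXCR4, had -0.58 (SE 0.0908) and rested on only 18 to 49 reads per library. At this level the pseudocount sets the size of the value, which was -1.04 with a pseudocount of 0.1 and -1.15 with edgeR. All 3 siCXCR4 values lay outside the range of the siNC values for each of these 12 genes. In GRCm38 coordinates, Ch25h lies on chromosome 19 at 34473786 to 34475135, Cd1d1 on chromosome 3 at 86995834 to 86999441, Mfge8 on chromosome 7 at 79133768 to 79149060 and Malat1 on chromosome 19 at 5795690 to 5802672.

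**Figure D1:**
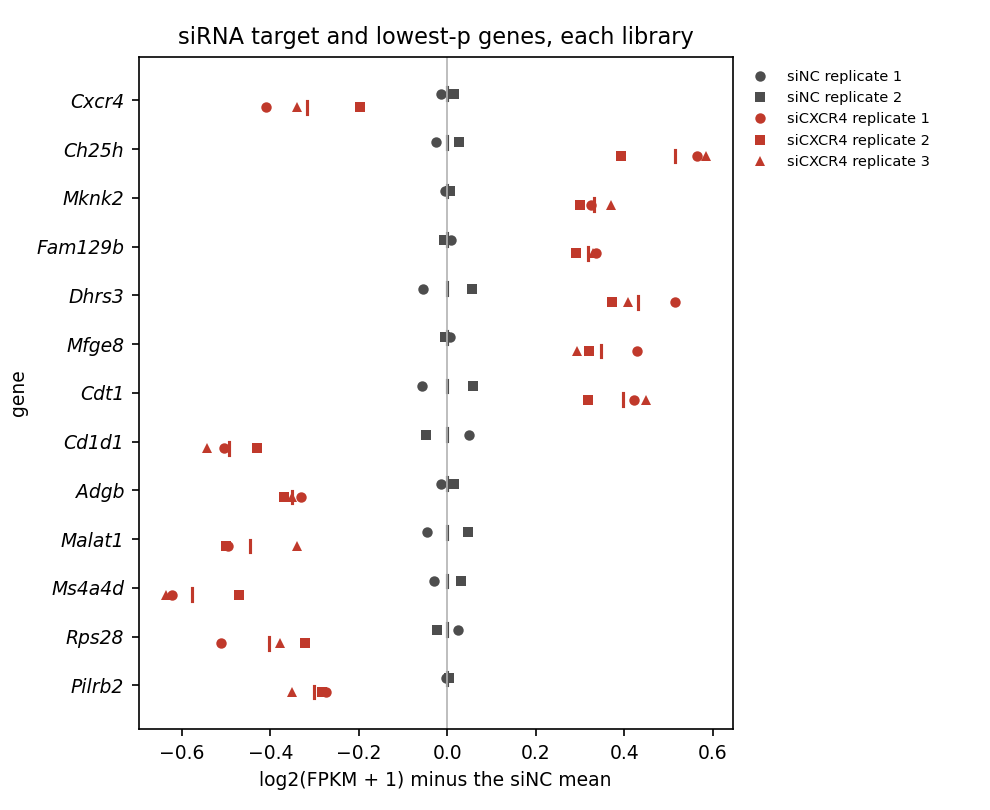
Level of Cxcr4 and of the 6 genes of lowest p in each direction, as log2(FPKM + 1) minus the siNC mean (x axis), for each gene (y axis). Each point is 1 library (grey siNC, red siCXCR4, shape for the replicate number) and short bars are group means; the mean for Cxcr4 lies at -0.32 and the siCXCR4 points of each gene lie on 1 side of both siNC points.

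Of the 17 genes that edgeR called on the whole reads, 11 were higher and 6 lower in siCXCR4. Malat1 had the smallest adjusted p (0.00722), followed by Adgb (0.0180), Apol7c and Cd1d1 (both 0.0267). Over all alternatives, the adjusted p of Malat1 ran from 8.70e-07 to 0.727. Apol7c was at 5.13 ± 0.464 FPKM in siNC and 2.64 ± 0.576 FPKM in siCXCR4, and Lst1, a leukocyte transcript of the major histocompatibility complex region, at 157 ± 12.7 and 123 ± 6.49 FPKM. Called as higher were also Nes, the intermediate filament nestin (2.59 ± 0.0157 and 3.73 ± 0.219 FPKM), and Cd180, a TLR4-related receptor (50.1 ± 1.40 and 63.1 ± 3.01 FPKM). Rassf8, Carhsp1 and Vsig8 were called as higher too, and with Apol7c, Lst1 and Nes these were chosen for naming after their values were seen. All 17 were also among the genes DESeq2 called. The edgeR count depended strongly on the libraries used: without siCXCR4 replicate 2 it was 312 genes, which held all 17, and without siCXCR4 replicate 1 it was 0. It was 5 without siNC replicate 1 (1 of them among the 17), 20 without siNC replicate 2 (5 among the 17) and 3 without siCXCR4 replicate 3 (1 among the 17). Among these genes and the 12 of lowest p, with Cxcr4, 8 of 20 overlap another gene with reads, and the strand setting of the counting is not given in the sources used here. For Carhsp1, the overlapping gene Pmm2 averaged 1079 reads against 883.

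Of 30 gene lists fixed before the data were examined, 28 had at least 5 measured genes, and camera with a preset correlation called 8, with 4 higher and 4 lower in siCXCR4. With an estimated correlation, camera called 0 of the 28, and fry, which asks whether the genes of a list move on balance in 1 direction, called 1. The count of 8 fell to 4 without siNC replicate 1 and to 4 without siCXCR4 replicate 1. No member of any list passed the limma test over all genes, so the members below are given as values.

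Lysosomal and phagocytic genes were higher in siCXCR4 as a list, with 29 of 34 measured members above 0 and a median log2 fold change of 0.10 (camera adjusted p = 0.00111, and adjusted p = 0.641 with an estimated correlation). At an unadjusted p under 0.05, 6 members were higher and 1 lower, and 0 passed when adjusted over the list alone. Lgmn, a lysosomal cysteine protease, was at 356 ± 11.7 FPKM in siNC and 415 ± 17.4 FPKM in siCXCR4. Grn, which encodes progranulin, was at 614 ± 1.37 and 716 ± 44.6 FPKM. The protease Ctsa had a log2 fold change of 0.18 (SE 0.0525), and the glycosidase Hexa had 0.14 (SE 0.0489). Fcgr2b, the inhibitory Fc receptor, lay the other way at 110 ± 2.33 and 99.9 ± 3.45 FPKM. The call held with any 1 library left out, with adjusted p between 0.000167 and 0.0443 by camera.

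Interferon-stimulated genes were higher as a list, with 35 of 49 members above 0 and a median of 0.06 (camera adjusted p = 0.00501, and adjusted p = 0.683 with an estimated correlation). By limma, 10 members were higher and 0 lower at an unadjusted p under 0.05, edgeR called 0 of those named here, DESeq2 called Cmpk2, and 0 passed when adjusted over the list alone. Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was at 437 ± 29.8 FPKM in siNC and 558 ± 53.5 FPKM in siCXCR4, and Usp18, which removes ISG15 from proteins, at 222 ± 5.87 and 257 ± 11.7 FPKM. The list members Mx2, annotated as a polymorphic pseudogene, Ifit1, Oasl1 and Ifi205 had log2 fold changes of 0.26 (SE 0.0954), 0.20 (SE 0.0754), 0.17 (SE 0.0537) and 0.17 (SE 0.0577). The list mean did not separate the groups, since siCXCR4 replicate 2 lay at -0.04 relative to the mean of the 5 libraries and siNC replicate 2 at 0.01. The call ended without siNC replicate 1 (adjusted p = 0.894), without siCXCR4 replicate 1 (adjusted p = 0.146) and with the copy counted as a siNC replicate, and over all alternatives adjusted p ran from 4.96e-07 to 0.894.

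Glycolytic and HIF-1 target genes were higher as a list, with 20 of 25 members above 0 and a median of 0.07 (camera adjusted p = 0.0129, and adjusted p = 0.641 with an estimated correlation). Of the members, 4 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Ldha, which makes lactate from pyruvate, was at 193 ± 3.16 FPKM in siNC and 216 ± 8.78 FPKM in siCXCR4, and Pfkfb3, which makes an activator of glycolysis, at 160 ± 7.51 and 185 ± 13.0 FPKM. The lactate exporter Slc16a3 and the prolyl hydroxylase P4ha1 both had a log2 fold change of 0.18. The call ended without siNC replicate 2 (adjusted p = 0.146) and without siCXCR4 replicate 1 (adjusted p = 0.0859), within a range of 0.00130 to 0.641 over all alternatives.

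Adhesion, migration and matrix genes were higher as a list, with 27 of 36 members above 0 and a median of 0.04 (camera adjusted p = 0.0454, and adjusted p = 0.641 with an estimated correlation). Among members, 10 were higher and 1 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Selplg, the P-selectin ligand, was at 41.5 ± 0.834 FPKM in siNC and 48.6 ± 3.47 FPKM in siCXCR4, and Thbs1, the matrix protein thrombospondin, at 25.7 ± 2.19 and 30.6 ± 2.31 FPKM. The protease Adam8 had a log2 fold change of 0.24 (SE 0.0721) and the protease inhibitor Timp2 0.21 (SE 0.0533). The integrin Itga4 lay the other way, at 16.4 ± 0.351 and 13.8 ± 1.56 FPKM. The call lay near the threshold: it ended without siNC replicate 2 (adjusted p = 0.221), siCXCR4 replicate 1 (0.162) or siCXCR4 replicate 2 (0.131), and with quantile normalization (adjusted p = 0.157), median scaling (0.0507), edgeR's values (0.0573), a mean of at least 5 FPKM, limma without trend or robust estimate, or ranks. Over all alternatives its adjusted p ran from 0.00489 to 0.641.

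Ribosomal protein genes were lower in siCXCR4 as a list, with all 40 measured members below 0 and a median log2 fold change of -0.15 (camera adjusted p = 3.86e-13, and adjusted p = 0.641 with an estimated correlation). Singly, 6 members were lower and 0 higher at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone, Rps28, at 21.4 ± 0.540 FPKM in siNC and 16.0 ± 1.13 FPKM in siCXCR4. Rps23 was at 155 ± 3.72 and 127 ± 11.9 FPKM, Rpl35 at 73.4 ± 6.20 and 56.9 ± 8.46 FPKM and Rplp1 at 525 ± 49.7 and 436 ± 42.3 FPKM. Genes of oxidative phosphorylation, the mitochondrial respiratory chain and ATP synthase, were lower as a list too, with 29 of 39 members below 0 and a median of -0.10 (camera adjusted p = 9.04e-05, and adjusted p = 0.641 with an estimated correlation). Of these, 1 was lower and 0 higher at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The cytochrome oxidase subunits Cox7c and Cox6c had log2 fold changes of -0.37 (SE 0.147) and -0.34 (SE 0.138), and the succinate dehydrogenase subunits Sdhd and Sdhb had -0.12 (SE 0.0533) and -0.10 (SE 0.0465), with Sdhd at -0.08 without siNC replicate 1. In both lists siCXCR4 replicate 2 lay among the siNC libraries: its mean level was 6.68 on the log2 scale for ribosomal proteins, against 6.77 and 6.68 in siNC and 6.56 and 6.43 in the other siCXCR4 libraries. The ribosomal call held with any 1 library left out, while that of oxidative phosphorylation ended without siNC replicate 1 (adjusted p = 0.132, in a range of 3.32e-09 to 0.641 over all alternatives). Ribosomal protein genes have many near-identical pseudogene copies, and how the authors counted reads matching several places is not given in the sources used here.

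Cholesterol synthesis genes were lower as a list, with 18 of 21 members below 0 and a median of -0.09 (camera adjusted p = 0.00501, and adjusted p = 0.660 with an estimated correlation). No member had an unadjusted p under 0.05 by limma, edgeR called 0 of those named here, and 0 passed when adjusted over the list alone. Mvd, an enzyme of the mevalonate pathway, was at 32.0 ± 3.68 FPKM in siNC and 28.8 ± 1.34 FPKM in siCXCR4, Fdft1, the squalene synthase, at 6.69 ± 1.16 and 5.66 ± 0.671 FPKM, and Lss, the lanosterol synthase, at 3.53 ± 0.209 and 3.21 ± 0.397 FPKM, with overlapping groups in each. The list mean of siNC replicate 1 lay at 0.19 and that of siCXCR4 replicate 2 at 0.11 above the mean of the 5 libraries, while siNC replicate 2 lay at -0.07. Without siNC replicate 1 the direction turned to higher (adjusted p = 0.736), and the call also ended without siCXCR4 replicate 1 (adjusted p = 0.0859) or siCXCR4 replicate 3 (0.0926), and with the copy counted as a siNC replicate. Over all alternatives it ran from 9.88e-09 to 0.736.

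**Figure D2:**
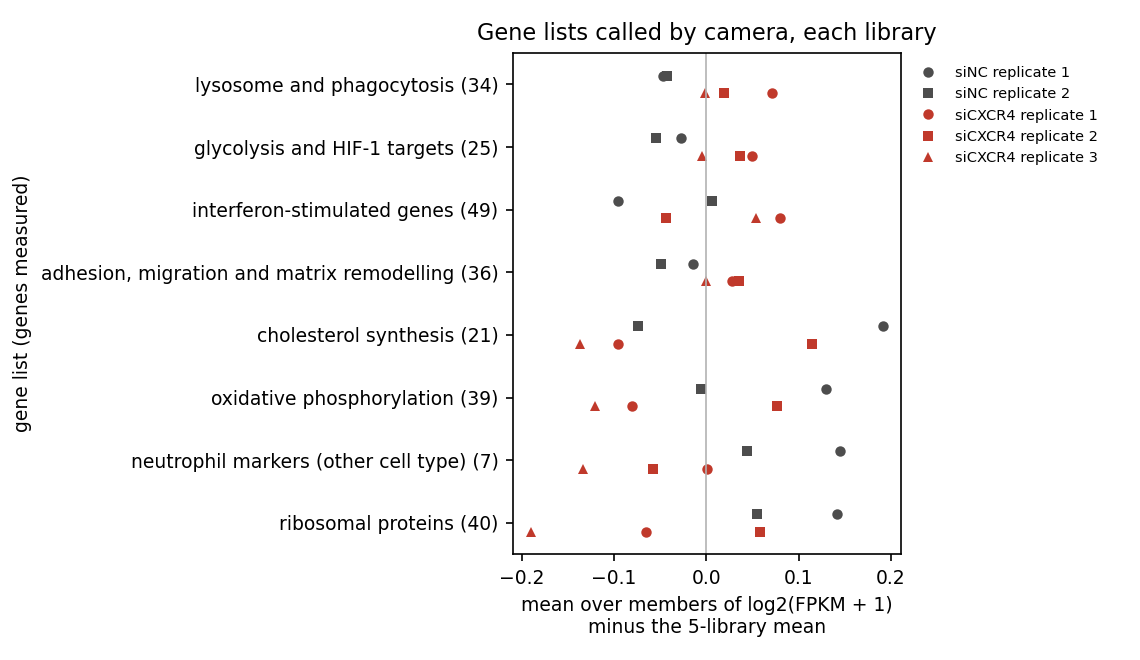
Mean over the measured members of log2(FPKM + 1) minus the mean of the 5 libraries (x axis) for the 8 gene lists that camera called with a preset correlation (y axis, genes measured in brackets). Each point is 1 library (grey siNC, red siCXCR4, shape for the replicate number); for ribosomal proteins siCXCR4 replicate 2 lies at 0.06, beside siNC replicate 2 at 0.06.

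Genes of proinflammatory cytokines were not called as a list (median -0.08, camera adjusted p = 0.0704), with 3 of 15 measured members lower and 0 higher at an unadjusted p under 0.05, and 0 passing when adjusted over the list alone. Il12a, a subunit of interleukin-12, was at 62.7 ± 4.37 FPKM in siNC and 44.0 ± 7.25 FPKM in siCXCR4, Il1b at 2083 ± 129 and 1626 ± 210 FPKM and Il1a at 1528 ± 82.7 and 1314 ± 127 FPKM. DESeq2 called Il12a and Il1b, both lower, and edgeR did not. Ebi3, a subunit of interleukin-27 and interleukin-35, was at 70.7 ± 3.65 and 78.5 ± 5.27 FPKM. Tnf (693 ± 47.6 and 667 ± 72.8 FPKM) and Il6 (26.1 ± 4.47 and 20.3 ± 5.13 FPKM), named after their values were seen as main products of LPS-treated macrophages, overlapped between the groups. The list of proinflammatory cytokines passed the threshold, as lower, without siCXCR4 replicate 2 (adjusted p = 0.000584) and in 5 of 20 alternatives in all, with adjusted p from 0.000584 to 0.641. Of 18 chemokine genes 1 was higher at an unadjusted p under 0.05 and 0 were lower, 0 passed when adjusted over the list alone, and the list was not called (adjusted p = 0.287). The higher gene, Ccl8, was at 2.58 ± 0.139 and 3.44 ± 0.448 FPKM and rested on only 27 to 39 reads per library (edgeR adjusted p = 0.690). Ccl22 was at 25.5 ± 1.66 and 20.8 ± 3.43 FPKM. Among 12 chemokine receptor genes and CXCR4 partners (adjusted p = 0.340), 1 was higher at an unadjusted p under 0.05 and 0 were lower, and 0 passed when adjusted over the list alone. Rgs1, a regulator of G-protein signalling, was at 19.3 ± 2.43 and 24.0 ± 0.949 FPKM and the G-protein subunit Gnai2 at 131 ± 9.77 and 146 ± 6.39 FPKM.

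Anti-inflammatory feedback genes were not called as a list (median 0.07, camera adjusted p = 0.105), but 3 of 24 measured members passed when adjusted over the list alone, all higher in siCXCR4. These were Atf3, a stress-induced repressor of inflammatory genes (145 ± 7.67 FPKM in siNC and 182 ± 10.6 FPKM in siCXCR4), Dusp1, a phosphatase that inactivates MAP kinases (114 ± 5.66 and 139 ± 6.56 FPKM), and the cytokine Il10 (18.1 ± 1.33 and 22.5 ± 1.45 FPKM). Zfp36, which destabilises cytokine mRNAs, had a log2 fold change of 0.22 (SE 0.0757), or 0.14 without siNC replicate 1, and did not pass. DESeq2 called Atf3 and Dusp1, and edgeR did not. In all, 4 members were higher and 0 lower at an unadjusted p under 0.05. The feedback list was called, as higher, without siNC replicate 2 (adjusted p = 0.00341) and without siCXCR4 replicate 2 (0.0361), in a range of 0.00341 to 0.818 over all alternatives. Of 26 TLR4 complex and adaptor genes 1 passed when adjusted over the list alone, Cd180, and the adaptor Ticam1 had a log2 fold change of 0.21 (SE 0.0506); 2 were higher and 0 lower at an unadjusted p under 0.05, and the list was not called (adjusted p = 0.343). Among 27 NF-kB subunits and regulators, 21 lay above 0 with a median of 0.03, 2 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. Camera did not call this list (adjusted p = 0.196) but fry did (adjusted p = 0.0327). Fry does not compare a list with other genes, and the median log2 fold change of all tested genes was 0.015. A shift in scaling shared by all genes is therefore not removed from the fry result. With no filter on low values camera called the NF-kB list too (adjusted p = 0.0186), in a range of 0.0186 to 0.641 over all alternatives. Its lowest p belonged to Tnip3, an inhibitor of NF-kB signalling, at 17.7 ± 0.396 and 20.5 ± 0.565 FPKM, and Zc3h12a, an RNase that degrades cytokine mRNAs, at 56.1 ± 1.21 and 64.9 ± 2.23 FPKM.

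Unfolded protein response genes were not called as a list (median 0.01, camera adjusted p = 0.623), with 14 members above and 13 below 0, but 3 of 27 passed when adjusted over the list alone, and 5 were higher and 1 lower at an unadjusted p under 0.05. These were Ppp1r15a, a subunit of the eIF2-alpha phosphatase (31.8 ± 0.277 FPKM in siNC and 38.4 ± 1.04 FPKM in siCXCR4), Sesn2, a stress-induced inhibitor of mTORC1 (32.9 ± 0.251 and 38.8 ± 1.17 FPKM), and the pseudokinase Trib3 (23.8 ± 3.01 and 30.0 ± 0.825 FPKM), whose log2 fold change of 0.32 was 0.20 without siNC replicate 1. The amino-acid synthesis enzyme Asns had a log2 fold change of 0.15 (SE 0.0509). Of 27 apoptosis genes (adjusted p = 0.276), 7 were higher and 1 lower at an unadjusted p under 0.05, with Bid at 13.3 ± 1.02 and 16.3 ± 0.987 FPKM, Trp53 at 11.0 ± 0.102 and 13.0 ± 0.911 FPKM and Pmaip1 at 12.5 ± 0.465 and 10.7 ± 0.299 FPKM. With no filter on low values the apoptosis list was called (adjusted p = 0.0436, in a range of 0.0436 to 0.641 over all alternatives). Of 20 immediate early and heat shock genes (adjusted p = 0.117), 5 were higher and 1 lower, and in both of these lists 0 passed when adjusted over the list alone. The AP-1 subunit Jund had a log2 fold change of 0.30 (SE 0.0706), the antiproliferative gene Btg2 0.21 (SE 0.0531) and the mitochondrial chaperonin Hspe1 -0.37 (SE 0.102). The list of immediate early and heat shock genes was called without siCXCR4 replicate 3 (adjusted p = 0.0390) and with no filter on low values, in a range of 0.0390 to 0.641 over all alternatives.

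The other lists of macrophage functions were not called by camera. Macrophage identity genes (25 measured, adjusted p = 0.215) included the lineage factor Spi1 at 177 ± 1.06 FPKM in siNC and 196 ± 7.59 FPKM in siCXCR4, and the glycoprotein Gpnmb at 1362 ± 31.6 and 1509 ± 35.6 FPKM. LXR and PPAR lipid handling genes (23 measured, adjusted p = 0.278) included the cholesterol exporter Abcg1 at 113 ± 3.02 and 126 ± 3.59 FPKM and the phospholipid transfer protein Pltp at 81.9 ± 6.86 and 103 ± 15.5 FPKM. Alternative activation genes (18 measured, adjusted p = 0.324) included the scavenger receptor Stab1, with a log2 fold change of -0.14 (SE 0.0529). Nitric oxide and oxidative burst genes (17 measured, adjusted p = 0.324) included Ptgs2, the inducible cyclooxygenase, with a log2 fold change of -0.19 (SE 0.0702), and Nos2, the inducible nitric oxide synthase, at 200 ± 29.2 and 240 ± 24.0 FPKM. Groups overlapped for Nos2, and its log2 fold change of 0.27 was 0.12 without siNC replicate 1 and 0.41 without siNC replicate 2. Inflammasome and pyroptosis genes (22 measured, adjusted p = 0.563) included the necroptosis kinase Ripk3, with a log2 fold change of 0.20 (SE 0.0488), and the inflammasome adaptor Pycard, with -0.25 (SE 0.0661). In the presentation lists, Ifi30, a lysosomal thiol reductase, was at 204 ± 8.82 and 239 ± 5.36 FPKM and the costimulatory ligand Cd86 at 38.4 ± 3.38 and 44.7 ± 3.02 FPKM (MHC class II, 13 measured, adjusted p = 0.623), and the immunoproteasome subunit Psmb9 had a log2 fold change of -0.12, or -0.07 without siNC replicate 2 (MHC class I, 22 measured, camera direction lower with a median of 0.01, adjusted p = 0.412). Cell cycle genes (17 measured, adjusted p = 0.403) included thymidine kinase Tk1, with a log2 fold change of -0.30 (SE 0.0750, and -0.49 with edgeR), and the replication helicase subunit Mcm6, with 0.19 (SE 0.0761). Nrf2 oxidative stress genes (25 measured, adjusted p = 0.412) included the peroxidase Prdx6, with 0.15 (SE 0.0603), and the transferase Gstm1, with 0.18 (SE 0.0739). At an unadjusted p under 0.05, 2 genes were higher and 0 lower in each of the identity, LXR and PPAR, MHC class II and Nrf2 lists, 0 higher and 1 lower in each of the alternative activation and oxidative burst lists, 1 higher and 2 lower in the inflammasome list, 1 and 1 in the cell cycle list, and 0 in the MHC class I list. In these 9 lists 0 genes passed when adjusted over the list alone. The Nrf2 list was called, as lower, without siNC replicate 2 (adjusted p = 0.0396) and without siCXCR4 replicate 2 (0.0129, in a range of 0.0129 to 0.977 over all alternatives).

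Of the lists of markers of other cell types, 1 was called. Neutrophil markers were lower in siCXCR4 as a list (7 of 18 listed genes measured, median -0.11, camera adjusted p = 0.0209, and adjusted p = 0.641 with an estimated correlation), and 2 passed when adjusted over the list alone. At an unadjusted p under 0.05, 2 were lower and 0 higher. These were S100a8 (16.8 ± 2.03 FPKM in siNC and 11.6 ± 1.47 FPKM in siCXCR4) and S100a9 (52.7 ± 0.291 and 41.9 ± 4.23 FPKM), calcium-binding proteins abundant in neutrophils and monocytes. The most abundant marker, the G-CSF receptor Csf3r, was at 110 ± 6.46 and 111 ± 7.09 FPKM. In RNA of all cells together, fewer neutrophils cannot be told from lower levels in macrophages. The neutrophil call ended without siNC replicate 1 (adjusted p = 0.132) or siCXCR4 replicate 2 (0.0963), with no filter on low values (0.259), with edgeR's values (0.0573), with the copy counted as a siNC replicate and with ranks, in a range of 0.00201 to 0.641. Dendritic cell markers were not called (7 measured, median -0.10, adjusted p = 0.0531), and included the transcription factor Batf3, with a log2 fold change of -0.37 (SE 0.102, and -0.57 with edgeR), and the most abundant member Itgax, with -0.06 (SE 0.0618), or 0.0103 without siNC replicate 1 and -0.12 without siNC replicate 2. The dendritic list was called, as lower, without siNC replicate 2 (adjusted p = 0.0180) and without siCXCR4 replicate 2 (0.0176), in a range of 0.0176 to 0.677 over all alternatives. Stromal and endothelial markers were not called (5 measured, adjusted p = 0.495), with the most abundant member Pdgfrb at 12.9 ± 1.70 and 11.3 ± 1.20 FPKM. Of lymphocyte markers 2 were measured, the more abundant Ighm at 5.52 ± 1.59 and 4.09 ± 0.286 FPKM. Of erythroid, mast cell and megakaryocyte markers 3 were measured, and Car2, a carbonic anhydrase, passed when adjusted over the list alone and was called by DESeq2, at 101 ± 4.31 and 127 ± 8.44 FPKM. Neither of the last lists had enough measured genes for camera with the filter on low values.

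The libraries also differed in the makeup of their RNA. Genes of microRNAs, small nuclear and small nucleolar RNAs took 57.1 ± 0.516 CPM in total in siNC (n = 2) and 46.9 ± 0.669 CPM in siCXCR4 (n = 3), 17.8% lower and without overlap, in the same direction as Malat1. Genes with at least 1 read numbered 19280 and 19072 in the siNC libraries and 18801, 18511 and 18520 in the siCXCR4 libraries. On the first principal component of the tested genes, which held 36.0% of the variance, the siNC libraries lay at -9.76 and -4.86, siCXCR4 replicate 2 lay near them at -3.45, and the other siCXCR4 libraries lay at 6.51 and 11.6. On the second component (23.5%), siCXCR4 replicates 1 and 2 lay together at -9.17 and -5.54, and siCXCR4 replicate 3 lay at 7.48, nearer the siNC libraries at 2.21 and 5.02. Each split of the 5 libraries into 2 and 3 was compared in the same way. The real split gave 17 genes called by edgeR, and setting siCXCR4 replicates 1 and 3 against the other 3 libraries gave 244.

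**Figure D3:**
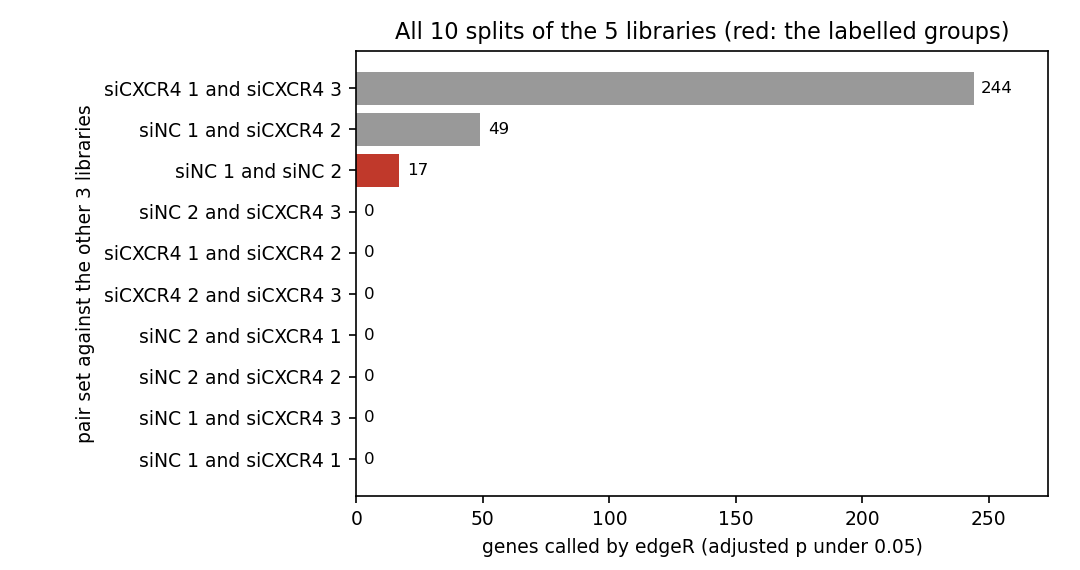
Number of genes called by edgeR on whole reads at an adjusted p under 0.05 (x axis) for each of the 10 splits of the 5 libraries into 2 and 3 (y axis, named by the pair of libraries). The real split gave 17 genes, siCXCR4 replicates 1 and 3 against the rest gave 244, and siNC replicate 1 with siCXCR4 replicate 2 gave 49.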

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

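The counts from DESeq2 and limma-voom, the copy counted as a replicate and the edgeR test with each library left out were chosen after the data were seen. The number of genes changed was 0 by limma, with 929 at an unadjusted p under 0.05. It was 17 with edgeR, 34 with DESeq2, 12 with limma-voom and 6 with the copy counted as a siNC replicate, and 0 to 2 with each library left out, the 2 without siCXCR4 replicate 2. The edgeR count ran from 0 without siCXCR4 replicate 1 to 312 without siCXCR4 replicate 2. The log2 fold change of Cxcr4 was -0.34 with DESeq2, where it passed the threshold, and kept its direction in every alternative run, from -0.38 to -0.27. The number of gene lists called, 8 by camera, was 4 with a replicate block, 5 with the copy counted as a replicate, 0 with an estimated correlation, 1 with fry, and 4 to 10 with each library left out. The replicate numbers are not shown to pair the samples; with the replicate block limma called 0 genes, and the calls lost were interferon-stimulated genes (adjusted p = 0.105), cholesterol synthesis (0.127), adhesion, migration and matrix remodelling (0.0612) and neutrophil markers (0.0663).

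Of 108 genes followed, 3 changed sign in some alternative. The Tnf log2 fold change was 0.00821 with a replicate block and -0.14 to 0.0102 with each library left out. The Csf3r log2 fold change was -0.0170 with a replicate block, -0.00397 with the copy, -0.00155 with edgeR, -0.00216 with limma-voom, and -0.0436 to 0.0754 with each library left out, and the Itgax log2 fold change was -0.12 to 0.0103 with each library left out. Lists that turned direction were chemokines (adjusted p = 0.845 with a replicate block, 0.0986 to 0.919 with each library left out), inflammasome and pyroptosis (0.977 with fry, 0.331 to 0.889), MHC class II presentation (0.166 to 0.857), MHC class I presentation (0.132 to 0.657), cholesterol synthesis (9.88e-09 to 0.736), oxidative stress defence (Nrf2) (0.492 with a replicate block, 0.0129 to 0.533) and unfolded protein response (0.688 with quantile normalization, 0.986 with a mean FPKM of at least 5, 0.199 to 0.877); the cause was not tested.

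Over all alternatives, values of these genes kept direction and side of the threshold in 1953 cases, newly passed it in 57 (24 with DESeq2, 17 with edgeR, 12 with limma-voom, 4 with the copy) and turned direction in 11. List values kept both in 480 cases, lost the call in 44, gained it in 18 and turned in 16. Leaving out 1 library moved the log2 fold change by over 1.5 times in 20 of the 108 genes (18 without siNC replicate 1, 11 without siNC replicate 2, 1 without siCXCR4 replicate 1, 4 without siCXCR4 replicate 2 and 6 without siCXCR4 replicate 3), and other alternatives did so in 11. Among the 20 were Nos2 (0.12 to 0.41 over all alternatives), Rgs1 (0.18 to 0.43), Cd86 (0.13 to 0.30), Thbs1 (0.16 to 0.33) and Rplp1 (-0.37 to -0.17). Where a siNC library was left out, the lone siNC library was assumed to vary like the siCXCR4 group. Leaving out siNC replicate 3 gave no separate value, since the copy was not used, and alternatives defined for counts only were not applied to FPKM.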

Other observations

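The gene sets of this part, the test of depth and the test of whether single libraries lay among the other group were chosen after the result was seen; the other tests were set down beforehand. Within the unfolded protein response list, the members linked to amino-acid stress and the transcription factor ATF4 were all above 0 in siCXCR4 (7 of 7, median log2 fold change 0.19), with 5 higher at an unadjusted p under 0.05. Ddit3, a stress-induced transcription factor, was at 47.8 ± 1.15 FPKM in siNC and 54.9 ± 3.49 FPKM in siCXCR4. Of the 14 endoplasmic reticulum chaperones and related members, 11 were below 0 (median -0.05), with Sdf2l1 at 43.3 ± 1.73 and 36.1 ± 4.35 FPKM. The difference between these sets was not tested.

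Of genes encoded in the mitochondrial genome, both ribosomal RNAs were above 0 (median 0.20), with mt-Rnr2 at 293 ± 9.93 FPKM in siNC and 354 ± 12.2 FPKM in siCXCR4 and mt-Rnr1 at 165 ± 4.83 and 181 ± 7.07 FPKM. Of 12 mitochondrial protein-coding genes 11 were below 0 (median -0.10), but their mean level did not separate the groups. On the log2 scale this mean was 6.70 in siCXCR4 replicate 2, above siNC replicate 2 at 6.69. The exception, mt-Nd3, a subunit of complex I, was at 8.82 ± 0.506 and 11.4 ± 0.683 FPKM (edgeR adjusted p = 0.565). By limma none of these passed the test over all genes, while DESeq2, added after the data were seen, called mt-Rnr2. In siNC, mt-Nd3, mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l averaged 5.36 to 12.1 FPKM, against 3326 FPKM for mt-Co1. How reads matching several places were counted is not given, so these low values may not follow RNA levels. The count of 11 below 0 includes mt-Co2, mt-Co3, mt-Atp6 and mt-Nd4l.

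Genes of microRNAs, small nuclear and small nucleolar RNAs took a 17.8% smaller share of reads in siCXCR4 than in siNC libraries. Unspliced RNA of host genes is a candidate explanation: noncoding features inside expressed protein-coding genes were lower by a log2 ratio of -0.27, more than features far from any such gene, with a difference of -0.17. These features could include the small noncoding genes themselves, which held 1217 reads in siNC replicate 1, against 12503 in the inside features. Inside meant within the span of a gene on either strand, so reads of introns and exons were not told apart. A difference in depth was argued against as the whole cause, since the depths of the groups overlapped while the shares did not. The libraries nearest in depth differed in this share by log2 ratios of -0.28 (replicates 1) and -0.31 (replicates 2), with depths 1.57% and 0.163% apart. The direction in these pairs was fixed beforehand, because the shares did not overlap. Genomic DNA carry-over stays open, because the far features were lower too, by -0.10. Whether the smaller share follows from the siRNA or from the handling of the samples was not tested.

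Ribosomal protein and oxidative phosphorylation genes were lower in siCXCR4 as lists with a preset correlation, and neither was called with an estimated correlation (adjusted p = 0.641 for both). Of 10000 random lists matched on deposited gene length and expression, 0% had a median as low, and 0% of those matched on GC and expression. Gene length and GC content were thereby argued against as the whole cause. The length of the transcripts present in the cells was not tested. Random lists drew genes singly, while members of these lists moved together (estimated correlation 0.79 and 0.56), so the 0% is no measure of chance. A difference between libraries that does not follow the groups may contribute: the highest siCXCR4 library, replicate 2, lay 0.00291 above the lowest siNC library in the ribosomal mean and 0.0824 above it for oxidative phosphorylation. An effect of the siRNA, also one that is weaker in that library, stays open.

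The 5 libraries can be split into 2 and 3 in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 929 genes and the highest other split 1394, with 3 of the 10 splits at or above 929, the real one included. For genes called by edgeR these were 17 and 244, with 3 of the 10 splits at or above 17, the real one included, and for lists called by camera 8 and 13, with 4 of the 10 at or above 8, the real one included. The split that set siCXCR4 replicates 1 and 3 against the rest called 244 genes, which points to a structure of the samples. By chi-square per gene, siCXCR4 replicate 1 was nearer replicate 3 (4.16) than replicate 2 (6.35). Over all tested genes, the SD of its log2 difference was as small against replicate 2 (0.197) as against replicate 3 (0.200). The siNC replicate 1 had a chi-square per gene of 4.20 against siCXCR4 replicate 2 and 4.84 against siNC replicate 2. For siNC replicate 2 against siCXCR4 replicate 2 it was 5.45. Without siCXCR4 replicate 2 the siCXCR4 and siNC groups gave 312 edgeR calls, which held all 17, so a difference between the groups that is weaker in that library is not told from a difference unrelated to the groups.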
